A study of Mus musculus with 12 samples.

How the data were processed

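Spleen RNA from 12 BALB/c mice was measured on 12 single-colour Agilent arrays, each holding 175906 non-control spots. Of the probes, 78070 had 2 spots and 19766 had 1. The deposited scanner files give a spot intensity on a linear scale, made with Agilent Feature Extraction 11.5.1.1 per the file headers, whereas the submitters' processing notes name version 9.1 of the same program. The column used was the processed signal, which that program had background-corrected. The spot flags (well above background, outlier, saturated) are other columns, written by the same program per the file headers. The authors also deposited a table of log2 values for 39027 catalogue probes. Set against the scanner files, each of its columns differed from the scaled signal computed here by 1 constant for that array (from 0.037 to 0.128, SD over probes 2.9e-10). Its scale is therefore log2 and its values are means over spots that were not flagged as outliers; the rule behind the constant is not given in the sources used here. Column medians lay between -0.959 and -0.874. Because that table holds the same measurements, using it in place of the scanner files changes only the array constants and the probe set, and it is not independent evidence.

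The processed signal was put on a log2 scale and the 75th percentile of each array was subtracted. Control spots and spots flagged as outliers were left out, and the spots of a probe were averaged. A probe with no spot left on any 1 array was not used, which left 97093 features. Probes were named only where their RefSeq accession, without its version, matched a table of the GRCm38.p6 assembly (4658 of 13019 RefSeq probes, 4290 genes) or where the array itself gives a name (27 probes). Catalogue, NONCODE, RIKEN clone, Ensembl and ultraconserved-element probes have no gene name here and each stayed a feature of its own. For a named gene with several probes the probe of highest mean was used. Whether a probe named for a pseudogene, or for a non-coding transcript of a protein-coding gene, also reads a coding mRNA was not checked. A feature was tested when its probe was well above background on every array of at least 1 of the 4 groups, which gave 72514 features, 2529 of them named. No non-control spot was saturated. Which gene lies nearest to a non-coding gene was taken from the same table, within 100 kb.

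All 12 arrays entered 1 limma model (limma 3.58.1 in R 4.3.3) with the 4 groups as terms and 8 residual degrees of freedom. Contrasts were tested with eBayes and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as threshold; every adjusted p below comes from limma. Gene groups were tested with limma's camera at an inter-gene correlation of 0.01, with an estimated correlation and with fry. The labels do not state how the mice were housed or processed in parallel. The p-values set each difference against the spread between spleens and arrays within the groups. Each group lay on 1 slide, as given below, so that spread holds no difference between slides. The p-values of comparisons across slides therefore take no account of such a difference. The number of arrays limits the precision, above all the 2 controls per day.

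The design was fixed before the data were examined, and so were 46 lists of protein-coding genes with 800 entries. Those lists could not be tested: 1 of their genes (Mx2) had a named probe among the tested features, and a minimum of 5 genes was set. None of the 14 genes that were to be reported in any case (cytokine, immunoglobulin, transcription factor, globin and proliferation genes) had a named probe. Groups of non-coding genes were written instead, after the names on the array were known and before any fold change was computed. The genes named below follow a rule fixed beforehand: for OVA against control on each day, the 6 highest and 6 lowest fold changes among named genes past the threshold whose OVA and control arrays did not overlap, or the 3 of largest moderated t where fewer than 3 passed; for the other comparisons the 4 highest and 4 lowest. Names of the Gm, LOC, Rik or clone type were left out, which left 176 tested genes to choose from. Members of gene groups named beside a group's counts fall outside this rule and were picked after their values were seen. No-overlap could not be asked of the difference between days.

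Per the file headers the arrays lay on 3 slides: slide 1 held all 4 controls, slide 2 the 4 OVA arrays of day 14 and slide 3 the 4 OVA arrays of day 28. Slide and group cannot be told apart for any comparison of OVA with control or between the OVA groups. The slide could not be entered as a block there; the control comparison lies within 1 slide.

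The model was tested on simulated data: 200 of the 72514 features were changed by known folds, with the spread of the real features. For OVA against control at day 28, 65.7% of the 2-fold and 93.9% of the 4-fold changes were recovered, with 12 unchanged features called. For day 14 these were 76.1%, 86.4% and 8, and 1.5-fold changes were recovered in 23.9% of cases. Both days had the same design there, so the gap between them reflects the random draw. The simulation had independent noise, no slide or array effect and 200 changed features, whereas 10191 features passed at day 28 in the real data. It therefore cannot show the false calls that a slide difference would add. Alternatives tried were quantile normalization, another percentile, the deposited log2 values, other filters, the mean of probes, other variance models, fewer groups in the model, blocks for replicate number and array position, leaving out each array, and a 2-fold minimum. Chosen after seeing the data were normexp on the median signal with an offset of 50 signal units (the mean signal was not used here), leaving out damaged spots or doubted arrays, scaling to spike-ins, and catalogue probes alone.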

Results

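The series measured RNA in the spleens of BALB/c mice injected with OVA (ovalbumin, an egg-white protein commonly used to sensitise mice) or with saline. OVA was given at 2 mg/kg in 3 injections, on days 1, 3 and 5, and spleens were taken on day 14 or day 28. There were 2 control and 4 OVA arrays on each day. The array carries catalogue probes together with large sets of non-coding transcripts: 31719 tested features were catalogue probes, 20457 NONCODE transcripts, 11990 RIKEN clones and 7566 RefSeq non-coding transcripts. Levels below are log2 signal relative to the array's 75th percentile. That percentile lay between 266.7 and 368.1 signal units on the control and day 14 OVA arrays and between 483.8 and 549.3 on the OVA arrays of day 28. Between 57.5% (OVA day 14 replicate 2) and 80% of spots were well above background. On control day 14 replicate 1, 3885 spots lay in a streak that departed from the other arrays, with a median excess of 2.27 on the log2 scale. The first principal component held 38% of the variance and set the OVA arrays of day 28 (56.4 to 81.2) apart from the other 8 arrays, which all lay below 0.

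**Figure D1:**
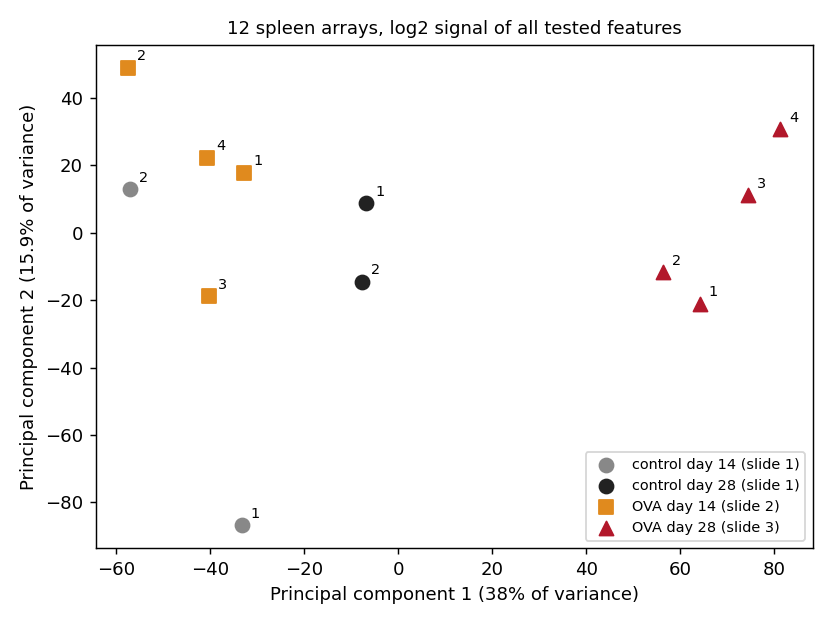
Each point is 1 of the 12 arrays, placed by its scores on the first (38% of variance) and second (15.9%) principal components of log2 signal; colour gives the group, shape the slide and the number the replicate. The 4 OVA arrays of day 28, all on slide 3, have scores from 56.4 to 81.2 on the first component, and control day 14 replicate 1 has the lowest score on the second, -86.8.

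The first question was how OVA spleens differed from saline spleens at day 14. Of 2529 named genes, 2 passed the threshold, both non-coding genes without an assigned role that fall outside the naming rule and were picked after their values were seen. Gm34699, beside Hapln1, was higher in OVA by 0.67 ± 0.10 (SE, log2, adjusted p = 0.0433, limma). Gm31089 was not well above background on the control arrays of day 14 and was nominally at least 2.53-fold higher on the OVA arrays (adjusted p = 0.0052). The OVA mean took all 4 arrays, 3 of which measured it, and the bound is explained below for Tvp23bos. With only the groups compared, and with the replicate block, 0 features passed at day 14, so neither call held there. Without a filter on dim probes, and with array weights, 1 feature passed, so at most 1 of these calls held. Scnn1b (a non-coding transcript of the gene for the beta subunit of the epithelial sodium channel) stood at -0.14 ± 0.12 (SD, n = 4) in OVA and -0.75 ± 0.11 (SD, n = 2) in control spleens, a 1.53-fold difference that did not pass (adjusted p = 0.0852, limma) except in 2 of 26 alternatives, probes well above background on all 12 arrays (0.0411) and trend and robust (0.04). Nctc1 and Kcnd3os, which lies opposite the potassium channel gene Kcnd3, had log2 differences of 0.54 and 0.64 and did not pass either (adjusted p = 0.0939 and 0.105), except in 2 and 1 of 26 alternatives. These were, for Nctc1, probes well above background on all 12 arrays (0.047) and leaving out control day 14 replicate 2 (log2 difference 0.64), and for Kcnd3os normexp (0.0467). Without control day 14 replicate 2 the only day 14 control left is replicate 1, the array with the streak. The normexp setting took the median signal in place of the processed signal, corrected its background by normexp and added an offset of 50 signal units; which of these moved a value was not tested, and an offset of that size shrinks the changes of dim probes. Among the 176 genes open to the naming rule, the lowest moderated t values belonged to Bach2os, Olfr1372-ps1 and Ager. Bach2os, beside Bach2, a transcriptional repressor of lymphocytes, differed by -0.57 on the log2 scale (adjusted p = 0.23, limma). For the pseudogene Olfr1372-ps1 no difference is given, since it was not well above background on any day 14 array. A non-coding transcript of Ager, the gene of the receptor for advanced glycation end products, differed by -0.41 (adjusted p = 0.303, limma). Ager turned to 0.02 with the normexp setting.

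Of all 72514 features, 49 passed at day 14 by limma, 45 of them higher in OVA, and 10678 had an unadjusted p under 0.05. With spike-in scaling the direction turned, with 13.7% of 124 features higher. All 8 spike-ins used read higher on the OVA arrays of day 14, by 0.125 to 0.392 on the log2 scale, 3 of them past adjustment. The spike-ins E1A_r60_3 and E1A_r60_a104, well above background in 83.6% and 23.8% of spots, were left out as dim and differed by 0.426 and 0.224. The balance of higher and lower features is therefore not settled here. Among the 7 non-coding genes studied in immune cells none passed: Ifngas1, the antisense neighbour of Ifng, differed by -0.14 ± 0.20 (SE), Morrbid by -0.04 ± 0.19, Zeb2os by -0.36 ± 0.17 and Mirt2 by -0.74 ± 0.34 on the log2 scale. Camera gave this group a p of 0.0161 downward (adjusted p = 0.21, and p = 0.0593 with an estimated correlation). None of 13 tested groups passed. The count rested on single arrays: it was 86 without OVA day 14 replicate 2 and 2 without OVA day 28 replicate 3. Without control day 14 replicate 2 the only control left on that day was replicate 1, the array with the streak, so the count of that fit rests on a damaged array. OVA and control lay on different slides.

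At day 28 the OVA spleens differed from controls in many more features. Zeb2os, the transcript opposite Zeb2, a zinc-finger transcription factor gene, was 1.79-fold higher in OVA (-1.14 ± 0.15, SD, n = 4, against -1.98 ± 0.18, SD, n = 2; adjusted p = 0.0102, limma). The pseudogene Gsdmcl2, beside the gasdermin gene Gsdmc4, was 1.56-fold higher (adjusted p = 0.0171). Tvp23bos was well above background only on the OVA arrays of day 28 and was nominally at least 1.98-fold higher there (adjusted p = 0.000159). This bound sets dim arrays at the lowest signal well above background. A probe can miss that call at a higher signal: on control day 14 replicate 1 Olfr1372-ps1 missed it at -4.505, while Ppp4r1l-ps had it at -4.635. The bound is therefore not guaranteed. The log2 change of Tvp23bos was 0.02 with the normexp setting. Cyp2d13, Zfp783 and Zfp410 were 1.9-fold, 1.92-fold and 1.92-fold higher (adjusted p = 0.0317, 0.0361 and 0.0454), and did not pass with normexp (adjusted p = 0.322, 0.711 and 0.865). Without control day 28 replicate 1 the calls of the 5 other than Tvp23bos did not hold: the log2 difference was 0.71 in Zeb2os (adjusted p = 0.0872), 0.42 in Gsdmcl2 (0.156), 0.97 in Cyp2d13 (0.121), 0.66 in Zfp783 (0.267) and 0.48 in Zfp410 (0.386), against 0.94 for Zfp410 with all arrays. Over all alternatives the calls of Zeb2os and Gsdmcl2 were lost in 1 and 2 of 26, and those of Cyp2d13, Zfp783 and Zfp410 in 8, 9 and 14 of 25.

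Lower in OVA at day 28 were Slc2a4rg-ps, a pseudogene beside the dendritic cell transcription factor gene Zbtb46 (1.62-fold, adjusted p = 0.0132, and 0.126 without control day 28 replicate 2), Prr33, beside Lsp1 (1.58-fold, adjusted p = 0.0282), Appbp2os (1.49-fold, adjusted p = 0.0316) and a non-coding transcript of Hnrnpa1, an RNA-binding splicing factor gene (1.39-fold, adjusted p = 0.0343). Celrr stood at 3.05 ± 0.13 (SD, n = 4) against 3.52 ± 0.10 (SD, n = 2; adjusted p = 0.0167), and Phxr4 was 1.36-fold lower (adjusted p = 0.0349). The call of Slc2a4rg-ps was lost in 1 of 26 alternatives and those of Prr33, Appbp2os, Hnrnpa1, Celrr and Phxr4 in 7, 9, 9, 5 and 8 of 26. Without control day 28 replicate 2 these 5 had log2 differences of -0.52, -0.74, -0.32, -0.40 and -0.42 (adjusted p = 0.199, 0.0672, 0.253, 0.124 and 0.165), and without control day 28 replicate 1 -0.81, -0.42, -0.63, -0.54 and -0.47 (adjusted p = 0.0654, 0.232, 0.0511, 0.0508 and 0.121).

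Transcripts beside immune genes went both ways at day 28, as did the named genes at large. Of all 2529 named genes 217 passed at day 28, 137 higher and 80 lower, so calls in both directions are not particular to these groups. Of 18 non-coding genes beside T cell genes, 1 rose and 1 fell: Gm40775, beside the cytokine gene Il22 (0.48 ± 0.09, SE, adjusted p = 0.00927), and Gm30989, beside Stat6, a transducer of cytokine signals (-0.49 ± 0.14, adjusted p = 0.0353). Of 10 beside myeloid and dendritic cell genes, Gm39266, beside the transcription factor gene Irf8, rose (0.72 ± 0.20, adjusted p = 0.0336) and Slc2a4rg-ps fell. These Gm genes fall outside the naming rule and were chosen after their values were seen. Of 7 snoRNA host genes Snhg7 fell (-0.37 ± 0.11, adjusted p = 0.0436), while Snhg8 differed by 0.38 ± 0.14 and did not pass (adjusted p = 0.0857). Of 103 transcribed pseudogenes 10 rose and 3 fell. Of 40 opposite-strand transcripts 2 rose and 1 fell. Of 32 non-coding transcripts of protein-coding genes 6 rose and 2 fell. No member passed among 6 imprinted genes, 11 beside erythroid, megakaryocyte and stem cell genes, or 18 beside inflammatory, interferon and stress genes; Ifngas1 differed by 0.15 ± 0.20. None of 13 groups passed camera at day 28, where the lowest p was 0.0786, for transcribed pseudogenes (p = 0.489 with an estimated correlation).

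In all, 10191 of 72514 features passed at day 28, 5395 higher and 4796 lower. Of these, 860 differed at least 2-fold, 769 of them higher; with normexp 211 were higher and 10 lower at that size. OVA and control arrays did not overlap in 42.2% of features, against 13.3% by chance. The share of higher calls moved from 52.9% to 75.3% of 5722 with spike-in scaling, so the balance of higher and lower features is not settled. It was 22.9% of 27650 with the normexp setting, whose offset can lower dim probes on the OVA arrays of day 28. The normexp share therefore cannot decide the balance. Without control day 28 replicate 2 the count was 1976 and without control day 28 replicate 1 it was 3353.

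**Figure D2:**
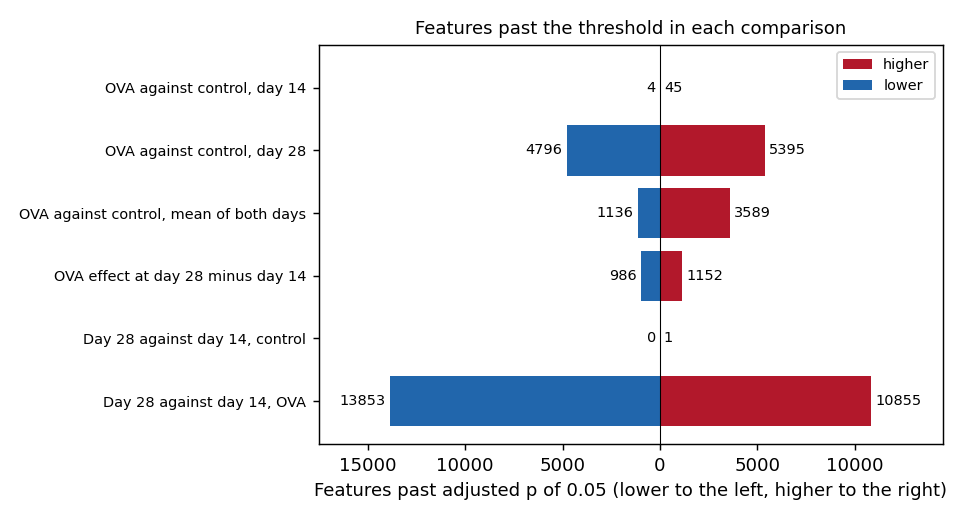
Bars give the number of features past an adjusted p of 0.05 in each of the 6 comparisons, higher to the right and lower to the left. The comparison of the OVA groups of both days has the longest bars (10855 higher, 13853 lower), and the control comparison has 1 feature.

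The mean effect averaged the effects of both days, so 1 day alone can carry it. Scnn1b was 1.45-fold higher in OVA (adjusted p = 0.0086, limma), without overlap on either day. Mtag2, Nctc1 and the pseudogene Marcksl1-ps4 were 1.29-fold, 1.27-fold and 1.27-fold higher (adjusted p = 0.0352, 0.027 and 0.0404), and Snhg7, a host gene of small nucleolar RNAs, was 1.23-fold lower (adjusted p = 0.0442). Scnn1b, Mtag2 and Snhg7 passed at day 28 but not at day 14. Nctc1 (log2 difference 0.54 at day 14 and 0.15 at day 28) and Marcksl1-ps4 (0.39 and 0.29) passed on neither day. The call of Scnn1b was lost in 1 of 25 alternatives (adjusted p = 0.0647 with the replicate block), but those of Mtag2, Nctc1, Marcksl1-ps4 and Snhg7 in 14, 11, 17 and 17 of 25, with adjusted p up to 0.134, 0.125, 0.192 and 0.113. Their log2 differences kept their sign, at 0.26 to 0.42, 0.20 to 0.39, 0.21 to 0.45 and -0.39 to -0.26. In total 4725 features passed, 3589 higher and 1136 lower; 3597 of them also passed at day 28 and 46 at day 14. With spike-in scaling 35.3% of 2362 were higher, against 76% here, and with normexp 51.5% of 8097. Without control day 28 replicate 2 the count was 1428. Across features, which are not independent replicates, the effects of both days had a Pearson r of 0.105. Of 45 features higher at day 14, 6 were also higher at day 28, against 3.3 for independent lists. Of 4 features lower at day 14, 0 were also lower at day 28, and 2 features passed on both days in opposite directions.

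**Figure D3:**
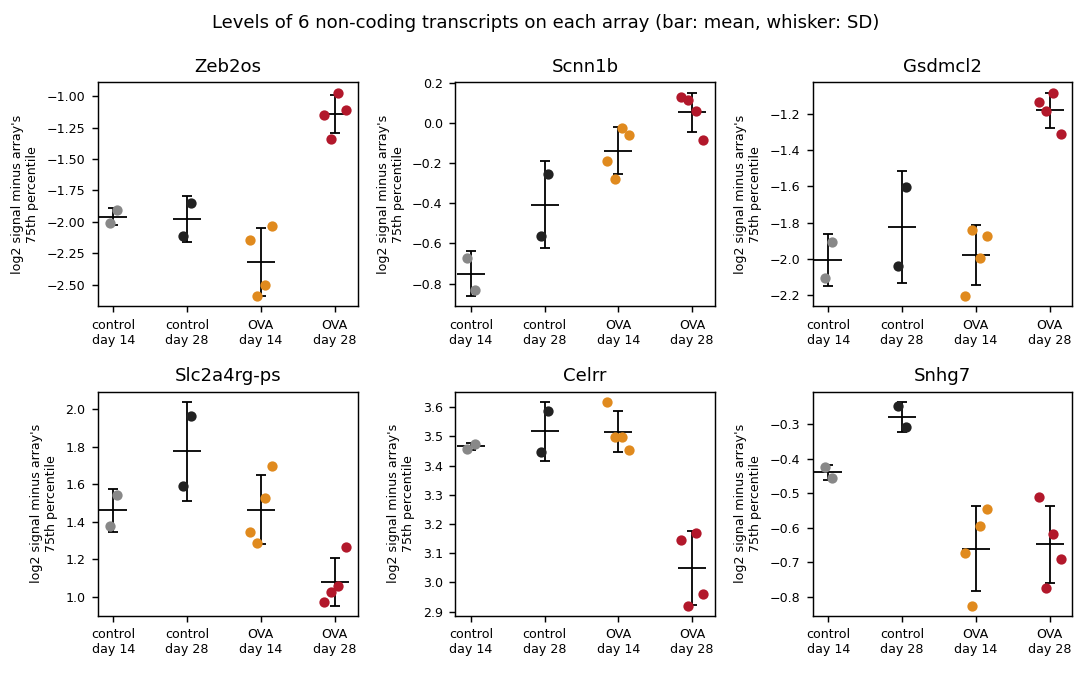
Points are single arrays, horizontal bars group means and whiskers SD, on a log2 scale relative to the array's 75th percentile, for 2 control and 4 OVA arrays on each day. Zeb2os is highest on the OVA arrays of day 28 (mean -1.14), and Snhg7 lies lower on the OVA arrays than on the controls on both days.

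The OVA effect differed between days for 2138 features by the interaction term, 1152 with a larger and 986 with a smaller value at day 28. The OVA arrays of each day lay on a slide of their own, so this term also sets slide 3 against slide 2. Of 8 spike-ins, 2 passed adjustment for it, with shifts from -0.681 to 0.118 on the log2 scale. A change of the OVA effect can therefore not be told apart from a slide difference. Zeb2os had a log2 difference of 1.20 ± 0.24 (SE, adjusted p = 0.0288), with -0.36 at day 14 and 0.84 at day 28; without control day 14 replicate 1 it was 1.25 and did not pass (adjusted p = 0.0675), and the call was lost in 11 of 25 alternatives (adjusted p from 0.00912 to 0.105). Rpph1, the RNA of the tRNA-processing enzyme RNase P, had -0.62 ± 0.14 (adjusted p = 0.0396), and the pseudogene Tmem181c-ps had -0.73 ± 0.17 (adjusted p = 0.0475). Both calls were lost in 18 of 25 alternatives, with -0.35 and -0.47 under spike-in scaling (adjusted p = 0.279 and 0.223), but kept their sign (-0.71 to -0.35 and -0.96 to -0.47). With array position as a block, 0 features passed. Of the counts with 1 array left out, only those without OVA day 14 replicate 1 (1861) and without OVA day 28 replicate 4 (1606) were within 1.5 times of 2138. The count was 732 without OVA day 14 replicate 3 and 610 without OVA day 28 replicate 1. Leaving out a control leaves 1 control on that day, and without control day 14 replicate 2 it is the array with the streak. The share with a larger value at day 28 was 98.3% of 3384 with spike-in scaling, 79.5% of 2197 with the percentile over probes well above background, 64% of 1698 with the deposited values and 14.8% of 22047 with normexp, against 53.9% here. The normexp share cannot decide a direction, since its offset can lower dim probes on the OVA arrays of day 28.

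Between days 14 and 28 the control spleens differed in 1 feature by limma, with 7461 at an unadjusted p under 0.05. It was the unnamed catalogue probe A_55_P2039284, which was higher at day 28 by 1.74 ± 0.15 (SE, log2, adjusted p = 0.00892) and was picked after its value was seen. No named gene passed. With array weights, with only the groups compared and with array position as a block the count was 0, so the call of A_55_P2039284 was lost there. Without control day 14 replicate 2 the only control left of day 14 was replicate 1, the array with the streak, so the count of that fit rests on a damaged array.

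Between days 14 and 28 the OVA spleens differed in 24708 features, 10855 higher and 13853 lower at day 28. Zeb2os was 2.26-fold higher (adjusted p = 0.000168, limma). Ppp4r1l-ps (a pseudogene), Zfp410 (a non-coding transcript) and Tvp23bos were not well above background on any OVA array of day 14. By the same nominal bound they were at least 1.81-fold, 1.85-fold and 1.27-fold higher at day 28 (adjusted p = 0.000478, 0.00037 and 1.63e-05). With normexp their log2 changes were 0.09 (adjusted p = 0.468), 0 (adjusted p = 0.967) and -0.21 (adjusted p = 0.00805). The offset of that setting can lower dim probes on the arrays of day 28, so neither these values nor its share of higher features decides a direction. Lower at day 28 were a non-coding transcript of Bcor, the gene of a corepressor of BCL6 (1.63-fold, adjusted p = 0.00172), Atad3aos (1.46-fold, adjusted p = 0.00355), megamind (1.73-fold, adjusted p = 0.00421, well above background on 3 of 4 arrays of day 14 and 2 of 4 of day 28) and Morf4l1-ps1 (1.52-fold, adjusted p = 0.00611). AW112010, a transcript studied in immune cells that falls outside the naming rule and was picked after its value was seen, was lower by 0.46 on the log2 scale (-0.46 ± 0.14, SE, adjusted p = 0.0256). The share of higher features was 43.9%, against 77.6% of 19257 with spike-in scaling and 19.5% of 47593 with normexp. These 2 groups lay on slides of their own, and 3 of 8 added spike-in RNAs also differed between those slides after adjustment, by up to 0.455 on the log2 scale.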

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

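The tests of quantile normalization, of damaged spots, of doubted arrays, of weak features and of single spleens had their predictions written before their results were seen; the tests of the spike-ins and of features split by their mean level were chosen after.

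Between the OVA arrays of day 28 and day 14, 24708 features passed. Only 1 of the 35 splits of the 8 OVA arrays gave as many, the real one, and the highest other gave 0. With 35 splits no smaller share than 1 of 35 is possible, so a chance split is argued against but not excluded. The real split is also the split by slide, so the count cannot say what sets the 2 groups apart. Scaling that depends on signal is argued against as the whole cause, since the count after quantile normalization was 102.8% of the main count. A slide, labelling or scan difference stays open: 3 of 8 spike-ins differed between the slides, slide 3 was brighter, and slide and group cannot be told apart. A biological difference between days stays open too and could not be tested apart from the slide.

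At day 14, 49 features passed, beside 10191 at day 28. The streak on control day 14 replicate 1 is argued against, since leaving out its spots gave 50. Leaving out that array and OVA day 14 replicate 2 gave 564, which is 5.53% of the main day 28 count and 4.28% of the day 28 count of the same model; the bound set beforehand was 5% and did not say which, so this remains open. The mean over both days had 4725 features; 2 of 100 splits within days gave as many, the real one and 1 that gave 8597. That share does not exclude chance for the mean effect of both days. The wrong split kept the real controls of day 28, and 3597 of the 4725 features also passed at day 28 but 46 at day 14. OVA and control also lay on different slides. A wrong grouping with more features than the real one points to a structure among the day 14 arrays. It exchanged control day 14 replicate 1 with OVA day 14 replicate 2. Its day 14 controls, control replicate 2 and OVA replicate 2, both lay at array position 2, and their deviations from the group means correlated at 0.316. The highest correlation, 0.37, joined control replicate 1 and OVA replicate 3 of day 14, at positions 1 and 3. Pairs at the same position had a median of 0.018 against -0.02 for the others. The day 14 controls correlated with the OVA arrays at their own position at 0.316, 0.252, 0.07 and 0.038, and the day 28 controls at 0.022, 0.014, -0.146 and -0.259. With 2 controls per day the deviations of 1 control mirror those of the other, so these correlations cannot decide on a position effect. With position as a block the mean effect had 2654 features. What sets that split apart stays open; an exchanged label was not tested.

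Of the 2-fold changes at day 28, 89.4% were higher in OVA. Features near the background are argued against as the whole cause, since the share was 97% (295 higher, 9 lower) among the 36257 features with the higher mean of the OVA and control levels of day 28, a choice that treats higher and lower features alike. It was 97.2% (375 higher, 11 lower) among features well above background on all 12 arrays, but that filter partly follows the change and left out 80 of the 91 lower features. With the normexp setting, which also changed the signal column and added an offset, 211 were higher and 10 lower. A single spleen, OVA day 28 replicate 4, is argued against, since the share was 90.7% without it. The slide stays open here as well.

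The difference between days was itself past the threshold for 2138 features, among them Zeb2os (1.20), Tmem181c-ps (-0.73) and Rpph1 (-0.62), as log2 differences of the OVA effect. These calls were lost in 11, 18 and 18 of 25 alternatives. Of 8 spike-ins, 2 also passed adjustment for this difference, by up to 0.681 in absolute log2 value, so the slide stays open here too. A fitted 1.60 for Tvp23bos is no measured size, since the probe was well above background only on the OVA arrays of day 28. The value turned to -0.21 with normexp, whose offset can lower dim probes on those arrays. Of 66 sets of 4 arrays examined for an array far from the other 3, 6 stood out, where chance gives about 1 in 20. OVA day 14 replicate 2 had 57.5% of spots well above background and a Cyp2d13 level of -4.11. OVA day 14 replicate 3 had a Morf4l1-ps1 level of -0.62. OVA day 28 replicate 4 had a Zfp783 level of -3.14, 1222 spots over 2 log2 units from the other arrays, and a 99th percentile of differences between repeated spots of 1.96. The control probes, which lie outside the 72514 tested features, were flagged only where higher in OVA. Human-PGK1_5 was higher in OVA at day 28 by 0.81 on the log2 scale, while the other PGK1 control probes differed by -0.04 (Mouse-PGK1_5) to 0.191 (Human-PGK1_3). At day 14 Human-GAPDH_5 was higher by 0.33 and the spike-in E1A_r60_1 by 0.32. The other GAPDH control probes differed there by 0.007 (Human-GAPDH_3) to 0.139 (Rat-GAPDH_5). Lower probes were not flagged, among them the spike-in E1A_r60_a20, which differed by -0.407 at day 28. At day 28 the 8 spike-ins differed by -0.407 to 0.509, 2 of them past adjustment.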

How the results depend on the processing

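Chosen after seeing the data were normexp, the streak's spots, both doubted arrays, spike-in scaling and catalogue probes alone; the rest was planned. Counts are given in the order day 14, day 28, mean of both days, difference between days, control days, OVA days, naming only counts over 1.5 times from the main ones (49, 10191, 4725, 2138, 1 and 24708); the cause was not tested except where fewer features or arrays entered. Within 1.5 times lay 4 of 29 settings for day 14, 16 of 29 for day 28, 10 of 28 for the mean, 8 of 28 for the difference, 15 of 29 for the control days and 25 of 29 for the OVA days. Quantile normalization gave 165 at day 14 and the other percentile 12. The deposited log2 values, on 31719 features, gave 23, 6116, 2855, 2 (control days) and 12563, and catalogue probes alone 5720, 2693, 2 (control days) and 12447, so most of that drop goes with the features tested. Without a filter the counts were 1, 5943, 2013 and 329; with probes well above background on all 12 arrays 267 at day 14, 3951 for the difference and 2 in controls; with trend and robust 232, 4278 and 2 for the same 3; with array weights 1 at day 14, 2425 for the mean, 495 for the difference and 0 in controls. With only the groups compared, day 14 and the control days had 0. A 2-fold minimum left 29, 860, 101, 774 and 1803 (OVA days). Normexp, here with the median signal and an offset of 50 signal units, so that 3 choices changed together, gave 260, 27650, 8097, 22047, 3 and 47593. Under it Olfr1372-ps1 and Ager turned to 0.12 and 0.02 at day 14, and Tvp23bos to -0.21 for the difference and for the OVA days. Spike-in scaling gave 124, 5722, 2362, 3384 and 2 (control days); it moved the median log2 change of all features from 0.046 to -0.184 at day 14 and from -0.063 to 0.081 for the OVA days, and normexp moved the latter to -0.226. Without both doubted arrays the counts were 564, 8477 (mean), 820 (difference) and 32 (control days). With the replicate block the counts were 0, 6652, 503 and 391. Whether the numbers pair the mice is not settled: 4 of 14 same-numbered pairs of arrays had deviations from the group means that correlated above 0.1 (median 0.01). With 2 controls per day the deviations of 1 control mirror those of the other, so this check cannot exclude a pairing. With array position as a block the counts were 2, 4165, 2654, 0 and 0 (control days). Leaving out single arrays gave 2 to 1978 at day 14, 1976 to 12185 at day 28, 1428 to 6028 for the mean, 282 to 5995 for the difference, 1 to 1562 for the control days and 19050 to 26621 for the OVA days; where 1 control array is left it is assumed to vary like the other groups. The highest of these counts for day 14, the difference and the control days came without control day 14 replicate 2. That fit leaves only replicate 1, the array with the streak, as control of day 14. Of 889 values of named genes under alternatives, 696 kept their side of the threshold, 184 lost it, 5 gained it and 4 turned. Added gene groups past the threshold numbered 0 on both days with camera, with an estimated correlation and with fry. Not run were the tests of the 46 lists fixed beforehand, normexp on the mean signal, and the slide as a block. Olfr1372-ps1 was not well above background on any day 14 array, so its value there has no measured size. Of Tvp23bos, Ppp4r1l-ps, Zfp410 and Gm31089, not well above background on any array of at least 1 group, the report gives nominal bounds for comparisons with that group.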

Other observations

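Of 12 non-coding genes beside developmental regulators, 2 were higher and 1 lower at day 28 than at day 14 in OVA, where 24708 of all 72514 features passed, so the group shows no excess: Halr1, at the Hoxa cluster, was higher at day 28 by 0.80 ± 0.21 (SE, log2, adjusted p = 0.0141, limma), Emx2os by 0.31 ± 0.08 (adjusted p = 0.0172), and Dmrta2os differed by -0.32 ± 0.11 (adjusted p = 0.0365). The imprinted gene Meg3 differed by -0.31 ± 0.10 (adjusted p = 0.0318) and Ftx, a transcript of the X-inactivation centre, by -0.35 ± 0.11 (adjusted p = 0.0304). The snoRNA host gene Snhg8 was higher at day 28 by 0.42 ± 0.11 (adjusted p = 0.0131). These genes were picked after their values were seen, and the slides of the OVA groups differ.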
